A study of Mus musculus with 11 samples.

How the data were processed

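The series measured RNA in mouse embryonic stem cells (ESCs) of strain 129S4/SvJae that were grown without feeder cells on gelatin, per the labels. Of its 11 samples, 7 are poly(A)-selected RNA libraries made with the directional dUTP method: 2 from wild-type cells (Dcr WT), 3 from separate lines that lack Dicer (Dcr KO lines 1, 3 and 4), 1 from cells with floxed cMyc alleles (cMyc flox) and 1 from cMyc knockout cells (cMyc KO). The Dcr libraries are paired-end and the cMyc libraries single-end, per the labels. The cMyc libraries come from another cell line than the Dcr libraries. The 4 chromatin immunoprecipitation libraries, for H3K4me3 and H3K36me3 in Dcr WT and Dcr KO, are not analysed here.

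The authors deposited 1 table for the Dcr libraries, with 48942 features, and 1 for the cMyc libraries, with 39889 features. TopHat, Bowtie and DESeq and the genome build mm9 are named in the submitters' processing notes, with no role, order or version; the counting tool, the gene models and any filter are not given in the sources used here. The deposited values are a normalised signal per feature, namely read counts divided by 1 factor per library, as the values themselves show. In each of the 7 columns, 100% of the values were whole multiples of the value of 1 read within 0.01 read, so whole reads could be recovered. Of the value columns, 0 could not be tied to a sample, and the column names carry a suffix (1 for the wild-type library 1, 2 for the other Dcr libraries) that no label explains. Depth was 101815723 and 206721717 recovered reads in Dcr WT libraries 1 and 2, and 247574902, 278006158 and 251808298 in Dcr KO lines 1, 3 and 4. The cMyc flox and cMyc KO libraries held 24660365 and 31633011. As to precision, a cMyc ratio from 12 and 28 reads, that of linc839, has an interval of 0.936 to 4.11, and that of Pou5f1 1.21 to 1.27. Whether the counting used strand is not given in the sources used here, so values of antisense and overlapping genes are uncertain, as are those of genes and repeats with near-identical copies.

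The tables prefix each feature with a source, from which classes were formed: coding features were taken as mRNAs, noncoding features as lncRNAs after setting aside 103 small RNA features in the Dcr table, and pseudogenes, repeat families, ribosomal RNA and unannotated loci as classes of their own. Which libraries the unannotated loci were assembled from is not given in the sources used here. RefSeq identifiers were given gene symbols from an annotation of GRCm38.p6, with 20183 of 20559 matched in the Dcr table and 16839 of 17123 in the cMyc table. That annotation was used for names only, and no coordinates are given because its build differs from mm9.

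Because the values were normalised before deposit, Dcr KO was compared with Dcr WT with limma 3.58.1 (R 4.3.3; empirical Bayes with trend) on log2(value + 1). Features with a value of at least 1 in at least 2 libraries were tested, 42358 in all, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The plan, written for either counts or normalised values, assigned this test to normalised values. Fold changes are on the log2(value + 1) scale, which understates the change of features near 0. The p-values measure the spread between these samples, and no label says that the wild-type replicates came from separate cultures. The share of lower calls was compared between lncRNAs and mRNAs with a two-sided Fisher's exact test across features, which are not replicates. The lncRNA median was set against 10000 random sets of mRNAs of the same size, matched on mean expression in 20 bins, and the odds ratio of lower calls was also taken over level bins with an exact conditional test.

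In total, 22 gene lists were fixed before the data were examined. They cover pluripotency, targets of ESC microRNAs, the microRNA machinery, microRNA host genes with the Dlk1-Dio3 locus, the Myc family, Myc targets, DNA methylation, G1/S control, p53 targets, interferon and antiviral genes, mesoderm and primitive streak, endoderm, neural ectoderm, trophoblast, fibroblasts, the germline, 2-cell-like cells, imprinted genes, known lncRNAs, TGF-beta and BMP signalling, ER stress with amino acid synthesis, and replication-dependent histones. They were tested with camera (preset inter-gene correlation 0.01, adjusted over the lists), with an estimated correlation and with fry, all in limma. Whereas camera sets a list against the other features, fry tests it against no change, so a pass in fry answers another question. The other features included 18313 unannotated loci, with a median log2 fold change of 0.40, against −0.06 for mRNAs. Such a background can make a list look lower than mRNAs and lncRNAs alone would. For DESeq2 and edgeR the lists were tested with cameraPR on the statistics of those tools. The rule for named genes, also fixed then, took Dicer1 or Myc, the genes Myc, Mycn, Pou5f1, Sox2 and Nanog, the 6 called mRNAs and 5 called lncRNAs with the largest change in each direction among those of above-median expression (against all features for mRNAs, against lncRNAs for lncRNAs, here and below) with every Dcr KO library on 1 side of every Dcr WT library, and up to 4 called members with the smallest adjusted p of each list that passed camera or had at least 3 called members. Other list members are named where few were called and were chosen after their values were seen.

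The cMyc libraries, 1 per genotype, allow no test. Their recovered reads were scaled with TMM factors (edgeR 4.0.16) from mRNAs and lncRNAs together, features with at least 10 reads over both libraries were kept, and log2 ratios used a pseudocount of 1 scaled read. Ratios of single genes have exact Clopper-Pearson 95% intervals, which cover counting error only. Medians have 95% binomial intervals over features, which cover the spread between features, taken as independent. Neither kind covers variation between samples. Lists and sets of features called in Dcr KO were placed among 10000 random sets of the same size matched on expression. For this comparison the rule named the 6 mRNAs and 5 lncRNAs with the largest ratio in each direction of above-median expression, and up to 3 members, by expression, of lists at or beyond the 2.5th or 97.5th percentile.

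The alternatives were other scalings, filters, pseudocounts and thresholds, DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, all Dcr libraries thinned to equal reads, small RNAs counted as lncRNAs, a narrower set of gene models, lists tested against mRNAs and lncRNAs alone, the known lncRNAs placed among random lists of other lncRNAs in the cMyc libraries, and the deposited scaling of the cMyc table. The limma procedure was tested on simulated counts for 42456 features with 200 changed: 2 of 50 features changed 1.5-fold were recovered, 13 of 50 at 2-fold, 26 of 49 at 4-fold and 39 of 50 at 8-fold, and 8 of the 88 calls fell on unchanged features. Among those with a mean of 100 or more, 10 of 23 were recovered at 2-fold and 23 of 25 at 4-fold. The 8 false calls of 88 are a larger share than the adjusted p threshold sets on average. Far fewer features were changed in the simulation than were called in the data (13444 of 42358). The Benjamini-Hochberg cutoff depends on that share, so the recovery rates do not give the power of the test in the data. Python 3.11.15 with pandas 2.3.3 prepared the tables.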

Results

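RNA was sequenced from wild-type mouse ESCs and from ESCs that lack Dicer, the enzyme that makes mature microRNAs, to compare the expression of lncRNAs and mRNAs. A second pair of libraries, from ESCs with floxed or deleted cMyc, belongs to the same series, whose title places Myc between microRNAs and lncRNAs. There were 2 Dcr WT libraries, 3 Dcr KO libraries from separate lines, 1 cMyc flox library and 1 cMyc KO library. In the Dcr libraries, mRNAs took 91.4 to 93.2% of reads and lncRNAs 2.12 to 2.67%. Ribosomal RNA took at least 28.1% of the reads of each cMyc library. Values are normalised read counts as deposited.

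Dicer1 itself was the first check of the genotype labels. Its normalised read count fell from 19462 ± 947 (SD, n = 2) in Dcr WT to 8696 ± 1033 (SD, n = 3) in Dcr KO, a log2 fold change of −1.17 ± 0.15 (SE; limma adjusted p = 0.000556). Neither the deleted part nor the part of the gene over which reads were counted is given in the sources used here. The reads that remained therefore cannot be taken to measure intact Dicer1 mRNA. Myc, the transcription factor named in the series title, fell 10.8-fold, from 9231 ± 2479 to 917 ± 422 (log2 fold change −3.44 ± 0.39, limma adjusted p = 0.000289). Its paralog Mycn was expressed above Myc in wild-type cells, at 86245 ± 9856, and did not pass the test (log2 fold change 0.13, adjusted p = 0.540). The core pluripotency factors Pou5f1 (0.18, adjusted p = 0.403), Sox2 (0.09, adjusted p = 0.626) and Nanog (0.48, adjusted p = 0.0958) did not pass either. Nanog stood at 147795 and 93760 in Dcr WT libraries 1 and 2 and overlapped between genotypes. Its log2 fold change was 0.81 without library 1, a fit that leaves 1 wild-type library. With scaling factors from mRNAs alone Nanog did pass (0.53, limma adjusted p = 0.0461).

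**Figure D1:**
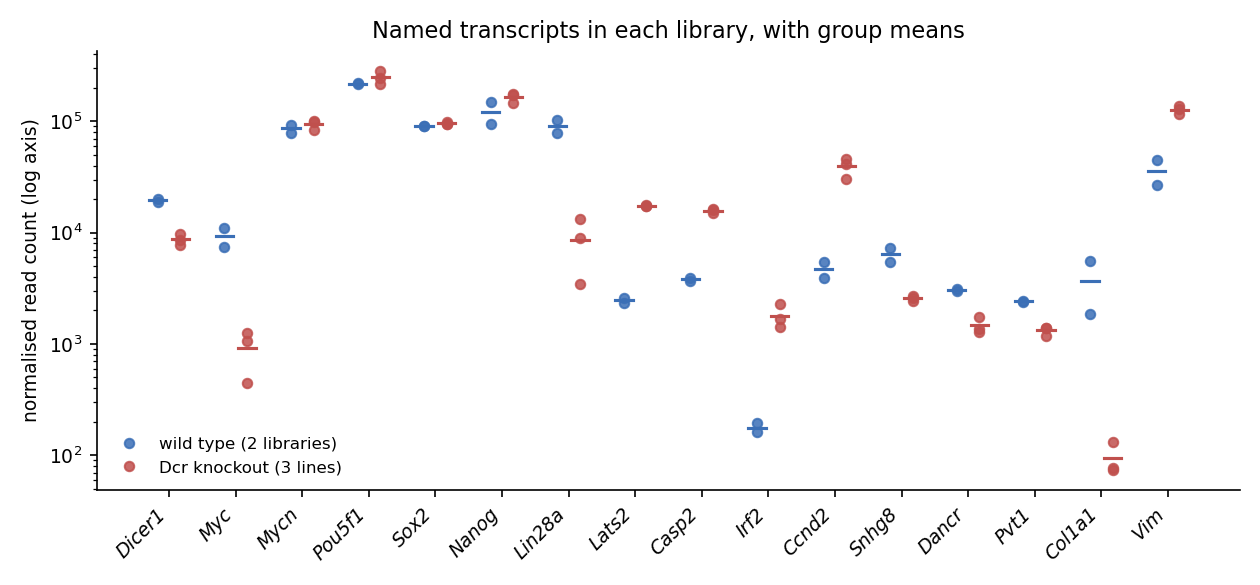
Normalised read counts of 16 named transcripts (log axis) in each of the 2 Dcr WT libraries and the 3 Dcr KO lines, with the mean of each group as a line. Myc, Lin28a and Col1a1 lie lower in each KO line, Lats2, Casp2, Irf2 and Ccnd2 lie higher, and Pou5f1 and Mycn overlap between genotypes.

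The loss of Dicer was accompanied by changes across the transcriptome. Of 42358 features tested, 7171 were higher and 6273 lower in Dcr KO (limma, adjusted p under 0.05). These included 3514 mRNAs that rose and 3885 that fell out of 17140, and 448 lncRNAs that rose and 722 that fell out of 4836. The balance of directions depended on the scaling, with 6268 features higher and 6955 lower under total count scaling and 7819 and 5796 under upper quartile scaling, where 58.7% and 47.4% of the mRNA calls were lower. Among mRNAs with a mean above the median of all features tested (54.1, far below the mRNA median of 2737), the largest increase was in Pou3f2, a neural POU transcription factor, from 0 and 19.2 in the wild-type libraries to 1233 ± 486 (SD, n = 3). Atp6v1b1, Tenm2, Cxcl17 and Fmo1 were also close to 0 in wild-type cells, at means of 1.83, 4.84, 2.47 and 2.92, and reached 302.5, 491.9, 243.8 and 218.2 in Dcr KO. The largest decrease was in the collagen gene Col1a2, at 292 and 1723 in the wild-type libraries and 1.65 ± 0.95 in the knockout lines. Matn3, an extracellular matrix gene, fell 66.4-fold and Plac8 fell 58.5-fold, from 2814 ± 1161 to 45.8 ± 9.8. Trim29 fell 61.5-fold, and Spink1 and Bpifb4 fell from means of 220.3 and 162.8 to 0.765 and 1.77. Each of these genes had an adjusted p of at most 0.000821 in limma. Leaving out a Dcr KO line lowered the number of calls, to 4386 higher and 4335 lower without line 1, 3782 and 3847 without line 3, and 4378 and 4275 without line 4. Dcr WT library 1 differs from the other libraries in an unexplained suffix of its column name, and without it 7545 features were higher and 5793 lower. Of 190 called genes that are named here or belong to a gene list, 62 were not called without some library, 36 had a fold that moved by over 1.5 times without some library, and 0 changed sign. Members named below for a lost call were chosen after their values were seen. Without Dcr WT libraries 1 and 2 in turn the log2 fold change was 5.87 and 10.2 for Pou3f2, 5.98 and 8.20 for Atp6v1b1, 6.99 and 5.60 for Cxcl17, −9.41 and −6.85 for Col1a2, and −6.53 and −5.35 for Trim29, and without Dcr KO line 1 that of Bpifb4 was −7.35.

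Targets of the microRNAs that ESCs express most strongly rose as a group in camera with a preset correlation between genes. With a correlation estimated from the data the list did not pass (camera adjusted p = 0.550), but no list passed that test, and this one had the smallest adjusted p. The estimate for this list, 0.0183, lay near the preset 0.01. That test therefore does not show that correlation between genes explains the rise. Of the 20 genes on that list, 14 rose and 0 fell (15 rose and 1 fell when adjusted over the list alone), with a camera adjusted p of 0.000195. At an unadjusted p under 0.05, 15 rose and 1 fell, and edgeR and DESeq2 each called 14 higher and 0 lower. Lats2, a kinase of the Hippo pathway, rose 7.02-fold from 2469 ± 179 to 17309 ± 195 (limma adjusted p = 1.15e-05). Casp2, which encodes caspase-2, rose 4.14-fold, Irf2 rose 9.92-fold and the nuclear receptor gene Nr2f2 rose 13.9-fold. The estimated correlation was the only one of 20 alternatives in which the list did not pass (adjusted p from 7.154e-15 to 0.550). Of its 14 calls, 3 were lost without some library: Wee1 without Dcr KO line 1 or 3 (adjusted p up to 0.0797), Bcl2l11 without line 1, line 3 or Dcr WT library 1 (up to 0.0826), and Cyld without any 1 line or library 1 (up to 0.0863). Genes of the microRNA machinery were split, with 7 rising and 3 falling out of 16 (8 and 3 adjusted over the list alone; camera adjusted p = 0.368, and from 0.0245 with fry to 0.874 over the alternatives). Tnrc6a and Ago1, components of the silencing complex, rose 3.70-fold and 3.24-fold, whereas Lin28a, which blocks let-7 maturation, fell 12.1-fold, and Dicer1 and Tarbp2 (−0.74) also fell. Of the 7 that rose, 3 lost their call without some library: Lin28b and Ago4 without any 1 line or Dcr WT library 1 (adjusted p up to 0.192 and 0.127), and Tnrc6b without line 3, line 4 or library 2 (up to 0.131).

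Cell-cycle genes that act at the G1/S boundary changed mostly upwards. Of 21 members, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a camera adjusted p of 0.0681. The list passed in 5 of 20 alternatives (adjusted p from 4.505e-05 to 0.628), among them the set test on DESeq2 statistics, on edgeR statistics (adjusted p = 0.0140) and against mRNAs and lncRNAs alone (adjusted p = 0.0223). The highest value, 0.628, was that of camera with an estimated correlation. Ccnd2, which encodes cyclin D2, rose 8.39-fold, from 4677 ± 1050 to 39338 ± 7926. The pocket protein gene Rbl2 rose 3.09-fold and the cell-cycle inhibitor gene Cdkn2a rose 3.20-fold, while Cdkn1c (log2 fold change −1.96) and Ccne1 (−0.93) fell. Among p53 targets, 2 rose and 6 fell out of 20 (camera adjusted p = 0.546). The 2 that rose were the inhibitor gene Cdkn1a (0.94) and Perp (0.52), and those that fell included Zmat3 (−0.99), the pro-apoptotic gene Bbc3 (−0.86) and Phlda3 (−0.68). Of 9 replication-dependent histone genes, 0 rose and 1, H2aw, fell (−0.79; camera adjusted p = 0.610). At an unadjusted p under 0.05, 2 histone genes rose and 1 fell, and edgeR and DESeq2 gave the limma counts. Without some library, calls were lost for 3 of the 11 G1/S genes that rose, 1 of the 2 p53 targets that rose, 4 of the 6 that fell, and the histone gene. Among G1/S genes these were Ccnd1 without Dcr KO line 1, line 3 or Dcr WT library 2 (adjusted p up to 0.137), Cdkn2b without any 1 line or library 1 (up to 0.281) and E2f3 without line 3 (0.0542). Among p53 targets they were Perp without line 3 (0.0973) or 4 (0.0506), Phlda3 without line 3 (0.0532), Mdm2 without any 1 line or library 2 (up to 0.0791), Fas without line 1, line 4 or library 2 (up to 0.0799) and Plk2 without line 1 (0.0556). H2aw was lost without line 3 (0.0748), line 4 (0.0812) or library 2 (0.0716).

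The Myc targets on the fixed list, most of them genes of ribosome assembly and nucleotide synthesis, fell more often than they rose. Of 37, 2 rose and 11 fell (3 and 12 adjusted over the list alone), with a camera adjusted p of 0.0933. Against mRNAs and lncRNAs alone the camera adjusted p was 0.318. At an unadjusted p under 0.05, 4 rose and 16 fell, edgeR called 3 higher and 16 lower, and DESeq2 3 higher and 12 lower. Odc1, the first enzyme of polyamine synthesis, fell 2.17-fold from 70752 ± 14235 to 32537 ± 4631, the ribosome assembly gene Mrto4 fell 2.21-fold and Tert, the telomerase reverse transcriptase gene, fell 1.94-fold. Hk2, which encodes hexokinase 2, rose 1.81-fold and the transferrin receptor gene Tfrc rose with a log2 fold change of 1.02. The list passed in 3 of 20 alternatives (adjusted p up to 0.874), namely on edgeR statistics, without Dcr KO line 1 (adjusted p = 0.0441) and with total count scaling (adjusted p = 0.0467). Of the 11 calls that fell, 5 were lost without some library: Cad without any 1 of the Dcr KO lines or Dcr WT library 2 (adjusted p up to 0.133), Rrs1 without any 1 line (up to 0.0608), Rcl1 without line 3, line 4 or library 1 (up to 0.0896), Nop16 without line 3, line 4 or library 2 (up to 0.0860) and Ddx21 without line 3 (0.0630). Within the Myc family, 1 of 11 members rose and 2 fell (camera adjusted p = 0.659): the Myc antagonist gene Mxd1 rose 1.93-fold, and Mycl fell 2.41-fold beside Myc. Of 15 genes of ER stress and amino acid synthesis, 1 rose and 5 fell (camera adjusted p = 0.374). Hspa5 (0.57) rose, and Phgdh (−1.61), Chac1 (−1.24), Atf3 (−0.91), Psat1 (−0.84) and Asns (−0.59) fell. Atf3, Psat1 and Asns were not called without Dcr KO line 3 (adjusted p = 0.0788, 0.0668 and 0.161) or line 4 (0.0709, 0.0540 and 0.137), Asns and Hspa5 not without Dcr WT library 1 (0.0626 and 0.0507), and Hspa5 not without line 1 (0.0924) or line 3 (0.107).

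Pluripotency genes as a list showed no common direction, with 5 rising and 3 falling out of 24 (camera adjusted p = 0.722). Klf2 (1.28), Gdf3 (0.93), Fgf4 (0.56), Nr0b1 (0.50) and Tfcp2l1 (0.49) rose, and Lin28a (−3.60), Dppa3 (−1.46) and Tdgf1 (−0.86) fell. Genes of DNA methylation also split, with 2 rising and 4 falling out of 12 (4 and 4 adjusted over the list alone; camera adjusted p = 0.659). Tet3, a methylcytosine dioxygenase gene, rose 4.81-fold and the maintenance methyltransferase gene Dnmt1 rose 1.63-fold. Dnmt3l, the cofactor of de novo methylation, fell 3.97-fold from 88452 ± 6025 to 24420.3 ± 11253, and Dnmt3b (−1.13), Tdg (−0.72) and Uhrf1 (−0.64) fell too. Several of these calls were lost without 1 library. Without Dcr KO line 1 they were those of Fgf4, Nr0b1, Tfcp2l1 and Tdgf1 (adjusted p = 0.0571, 0.144, 0.125 and 0.0591), and without line 3 the same 4 (0.0824, 0.161, 0.115 and 0.0661), Dnmt1 (0.0560) and Uhrf1 (0.0620). Tfcp2l1 and Tdgf1 were also lost without line 4 (0.0658 and 0.0918), Nr0b1 and Tfcp2l1 without Dcr WT library 2 (0.0675 and 0.104) and Tdgf1 without library 1 (0.0597). The median, mean and test of a list differed in sign for pluripotency genes, the Myc family, trophoblast and germline genes, and camera and fry differed in direction for DNA methylation.

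**Figure D2:**
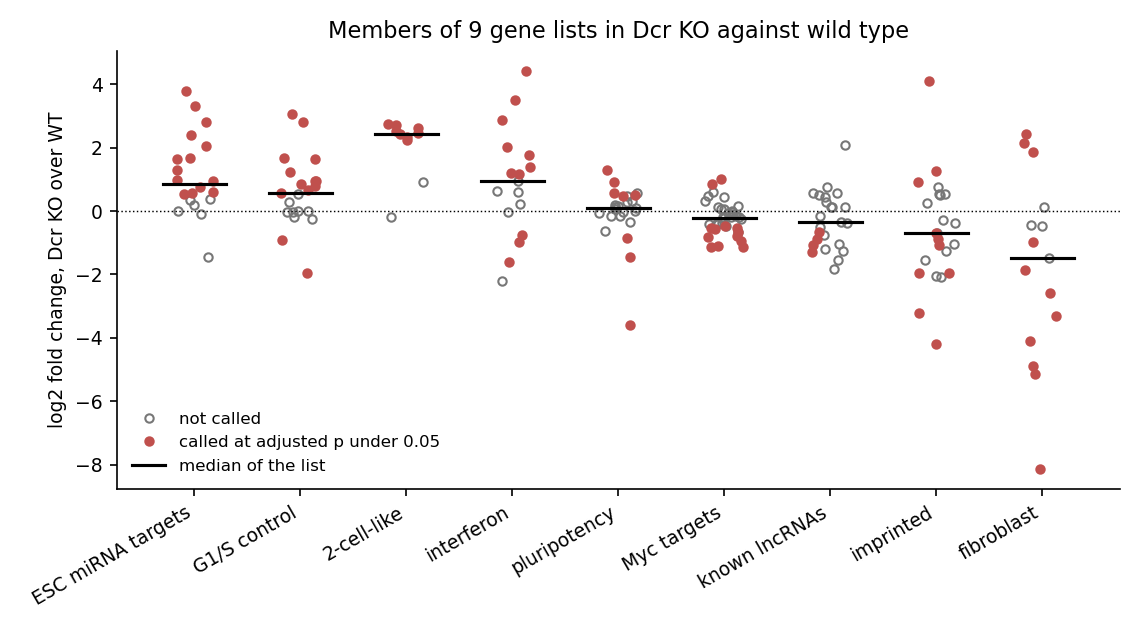
Log2 fold change in Dcr KO over Dcr WT for the members of 9 gene lists, with members called by limma (adjusted p under 0.05) filled, others open and the median of each list as a bar. The ESC microRNA targets have a median of 0.85, the 2-cell-like genes 2.44 and the fibroblast genes −1.47.

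Markers of differentiated lineages moved in both directions within each list. Of 15 mesoderm and primitive streak genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.181). The VEGF receptor gene Kdr rose 22.7-fold from 299 ± 92 to 6898 ± 2272, and Evx1 (4.71), Gsc (1.36) and Wnt3a (1.24) rose. Among the 7 that fell were T (−5.26), Fgf8 (−4.86), Mesp2 (−2.13), Mesp1 (−1.42) and Nodal (−0.57). Without Dcr WT libraries 1 and 2 in turn T was at −4.28 and −6.23. Of 17 endoderm genes, 4 rose and 5 fell (camera adjusted p = 0.553). The basement membrane genes Sparc (1.77), Lamc1 (1.16), Col4a2 (1.06) and Col4a1 (0.66) rose, and Hnf4a (−3.82), Amn (−2.11), Gata6 (−2.01), Cubn (−2.00) and Sox7 (−1.64) fell. Of 16 neural genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.546): Pax6 (2.93), Neurog1 (2.63), Ncam1 (2.30), Otx2 (2.05) and Map2 (0.70) rose, and Fgf5 (−3.02) and Nes (−0.55) fell. Pax6 did not pass edgeR on the recovered reads (adjusted p = 0.0614), and it stood at 1044 and 231 in the 2 wild-type libraries, so that its log2 fold change was 4.01 without Dcr WT library 1 and 1.84 without library 2; for Ncam1, at 7757 and 3225, it was 2.93 and 1.67. Of 13 trophoblast genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.631), with Elf5 (3.26), Gata3 (2.58), Fgfr2 (1.04) and Tfap2c (0.82) higher and Cdx2 (−2.04) and Ascl2 (−0.84) lower. Fibroblast markers moved with the same genotypes: of 15, 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0543). Col1a1 fell from 3691 ± 2580 to 94.0 ± 32.4 beside Col1a2, Acta2 (−4.89), Tagln (−3.31) and Thy1 (−1.86), whereas Vim rose 3.67-fold from 35788 ± 12633 and Dcn (2.44) and Col5a2 (2.14) rose. The fibroblast list passed in 7 of 20 alternatives (adjusted p from 0.0136 to 0.628), which include the sets without Dcr KO line 1 (adjusted p = 0.0441) or line 3 (adjusted p = 0.0453). Against mRNAs and lncRNAs alone the list did not pass (camera adjusted p = 0.166). Among the called lineage and fibroblast genes, calls were lost without any 1 of the Dcr KO lines for Gsc (adjusted p up to 0.112), Mesp1 (up to 0.0770), Cubn (up to 0.150) and Ascl2 (up to 0.121), without line 1 or 3 for Dcn (0.0839 and 0.0715), without line 1 or 4 for Gata6 (0.0895 and 0.0566), without line 3 for Tfap2c (0.0523), without line 4 for Cdx2 (0.0577), and without line 3 or 4 for Nes (up to 0.142) and Nodal (up to 0.0824). Without Dcr WT library 1, Cubn (−0.69), Gata6 (−1.26) and Cdx2 (−1.41) were not called, and without library 2, Gsc (0.66), Ascl2 (−0.54) and Mesp1 (−1.34) were not. Without the other of the 2 libraries Cubn was at −3.31, Gata6 at −2.76, Cdx2 at −2.67 and Gsc at 2.07. Col1a1 was at −5.91 and −4.35, and Col1a2 at −9.41 and −6.85, without libraries 1 and 2, and without line 4 Acta2 was at −3.94 and Tagln at −2.64 (Acta2 at −5.49 without line 1).

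Antiviral genes rose more often than they fell, with 8 higher and 3 lower out of 17 (8 and 4 adjusted over the list alone; camera adjusted p = 0.181). The list passed in 2 of 20 alternatives (adjusted p from 0.00834 to 0.874), namely fry, which tests against no change, and the set test on DESeq2 statistics. Rsad2, which encodes viperin, rose 21.5-fold from 39.4 ± 10.2 to 880.7 ± 251, the double-stranded RNA sensor gene Ifih1 rose, and the signalling gene Irf9 rose 4.06-fold. Bst2 fell 3.01-fold, and Dhx58 (−0.98) and Stat2 (−0.76) also fell. Genes of the 2-cell-like state rose in 8 of 10 cases and 0 fell (camera adjusted p = 0.0543). At an unadjusted p under 0.05 the counts were also 8 and 0, DESeq2 called 6 higher and 0 lower, and edgeR only 2 higher and 0 lower. The list passed in 8 of 20 alternatives (adjusted p from 0.000326, without Dcr WT library 1, to 0.874), but not on DESeq2 or edgeR statistics. Zscan4c, Zscan4d, Gm5662 and Gm4340 rose between 5.34-fold and 6.56-fold, but the wild-type libraries differed widely (Zscan4c at 950 and 174), these genes share reads with close copies, and neither edgeR nor limma without Dcr KO line 4 (adjusted p = 0.0597) called Zscan4c. Of 17 TGF-beta and BMP genes, 7 rose and 5 fell (camera adjusted p = 0.610), with Tgfbr2 (2.39), Id2 (2.03) and Lefty1 (1.28) among those that rose, and Bmp4 (−2.85), Tdgf1, Smad7 (−0.76), Nodal (−0.57) and Id3 (−0.51) lower. Of 16 germline genes, 3 rose and 3 fell (camera adjusted p = 0.760): Syce1 (0.98), Rpl10l (0.82) and Ddx4 (0.80) rose, and Tdrd5 (−2.48), Sycp3 (−0.85) and Mael (−0.72) fell. Of the 8 calls among 2-cell-like genes, 7 were lost without some library, as were 3 of the 11 antiviral and 4 of the 6 germline calls. Calls were lost without any 1 of the Dcr KO lines for Id3, Tdgf1, Syce1 and Sycp3 (adjusted p up to 0.129, 0.0918, 0.0710 and 0.136), for Isg15 and Acvr2a (up to 0.128 and 0.122) and for Zfp352 (up to 0.101), without line 3 or 4 for Tdpoz4 (up to 0.112), without line 1 or 4 for Zscan4f (up to 0.0844), without line 1 for Dhx58 (0.0626), Smad7 (0.0540) and Rpl10l (0.0696), without line 3 for Oasl1 (0.0554), Dhx58 (0.0560), Nodal (0.0824) and Mael (0.0740), and without line 4 for Usp17lc (0.0590), Gm4340 (0.0501), Zscan4d (0.0569), Nodal (0.0614), Rpl10l (0.0576) and Mael (0.0794). They were also lost for Id3 (0.127), Tdgf1 (0.0597), Isg15 (0.0815) and Acvr2a (0.112) without Dcr WT library 1 and for Sycp3 (0.170), Mael (0.0658) and Tdpoz4 (0.0698) without library 2. Without libraries 1 and 2 in turn the log2 fold change was 2.89 and 4.12 for Ifih1, 3.83 and 1.40 for Zscan4c, 3.53 and 1.30 for Zscan4d, 3.10 and 1.83 for Gm5662, and 3.91 and 1.51 for Gm4340.

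Imprinted genes changed in both directions. Of 23, 3 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.374, and from 0.0278 with fry to 0.874 over the alternatives). Plagl1, a zinc finger transcription factor gene, rose 17.3-fold from 1781 ± 674 to 29872 ± 2922, and Zrsr1 (1.28) and Ndn (0.92) rose. Phlda2, a growth restraint gene of the placenta, fell 18.2-fold from 22101 ± 7642 to 1195 ± 249, Magel2 fell 9.29-fold and Cdkn1c fell 3.89-fold. Of the 7 that fell, 2 lost their call without some library: Mest without any 1 of the Dcr KO lines or Dcr WT library 1 (adjusted p up to 0.0697) and Grb10 without line 3, line 4 or library 1 (up to 0.0948). Of 11 microRNA host genes and Dlk1-Dio3 genes, 1 rose and 2 fell (camera adjusted p = 0.439): Mcm7 (0.54) rose, and Sfmbt2 (−1.97) and Dlk1 (−1.95) fell. The knockout lines differed at the Dlk1-Dio3 locus, where Meg3 and Rian stood far lower in line 1 than in lines 3 and 4 (values at the end of the text). Mcm7 lost its call in 7 of 19 alternatives, among them pseudocount 0.1 (adjusted p = 0.0521), leaving out any 1 of the Dcr KO lines (0.0525 to 0.132) and leaving out Dcr WT library 2 (log2 fold change 0.35, adjusted p = 0.122). The same counts were found adjusted over the list alone for 11 of the 22 lists, namely those for which no second pair of counts is given.

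The comparison the design names is that of lncRNAs with mRNAs. Among known lncRNAs, 4 of 24 fell and 0 rose in limma (camera adjusted p = 0.480). At an unadjusted p under 0.05, 6 fell and 3 rose, edgeR called 4 lower and 0 higher, and DESeq2 6 lower and 0 higher. These were Snhg8, a host of small nucleolar RNAs, from 6380.5 ± 1262 to 2572 ± 140 (2.46-fold), Dancr (2.09-fold), Pvt1, the neighbour of Myc (1.83-fold), and the X-linked Firre (1.58-fold), which did not pass without Dcr KO line 1 (adjusted p = 0.0805) or line 4 (adjusted p = 0.0684). The abundant nuclear lncRNAs Malat1 (0.29) and Neat1 (0.56) did not pass. Among all lncRNAs of above-median expression, the largest decreases were in uc007uiz.1 (535 ± 34 to 10.5 ± 7.0), AK137524, Gm5091, uc008oht.1 and AI662270 (879 ± 321 to 27.7 ± 12.4). The largest increases were in 2410024F20Rik (0 and 11.9 in the wild-type libraries, 185 ± 75 in Dcr KO), 4930590L20Rik, AK038409, uc008llj.1 and uc008wdg.1, all with wild-type means of at most 5.93. Each of these 10 lncRNAs passed limma, with adjusted p-values from 6.58e-05 to 0.00405. Without Dcr WT libraries 1 and 2 in turn the log2 fold change was −4.79 and −6.55 for AK137524, −4.51 and −6.31 for Gm5091, 3.75 and 7.44 for 2410024F20Rik, 7.01 and 3.54 for 4930590L20Rik, 3.80 and 6.01 for AK038409, 5.84 and 3.51 for uc008llj.1, and 3.39 and 5.87 for uc008wdg.1. Without Dcr KO line 1 it was −5.99 for uc008oht.1 and 5.22 for uc008wdg.1.

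Called lncRNAs were lower more often than called mRNAs were. Of the lncRNA calls 61.7% were lower, against 52.5% of the mRNA calls. The odds ratio was 1.46 (95% interval 1.28 to 1.66, Fisher's exact test across features, p = 4.14e-09). A locus can be listed under more than 1 record, so features are not independent and this interval may be too narrow. The median log2 fold change was −0.22 for lncRNAs and −0.06 for mRNAs, and the difference between them was −0.24, −0.12 and −0.06 in lines 1, 3 and 4, with a mean of −0.14 ± 0.09 (SD, n = 3). Between the wild-type libraries alone, library 2 against 1, it was 0.08, larger in size than in line 4. The lncRNAs were expressed at a median of 34.5, far below the 2737 of mRNAs, and weakly expressed mRNAs fell further than strongly expressed ones. Random sets of mRNAs matched to the lncRNAs on mean expression had a median of −0.45 (95% of sets between −0.49 and −0.40). The lncRNAs lay 0.23 above the median of these sets and above all 10000 of them. The p of this random-set comparison across features is given as 1e-04, a floor set in advance. In simulated data without change, 2 of 20 draws lay outside the central 95% of matched sets, with shifts of at most 0.028. At the levels of the called lncRNAs, 66.3% of mRNA calls were lower. The odds ratio over level bins was 0.841 (95% interval 0.728 to 0.971, exact conditional test across features, p = 0.0165). By level, called lncRNAs were lower less often than called mRNAs below a mean of 1000. Between 1000 and 10000 the shares were 55.0% and 54.2%, and above 10000 lncRNAs were lower more often (15 of 18 calls, against 31.2% of mRNA calls). The direction of the raw difference held without Dcr WT library 1, the only library with its column suffix (58.0% of lncRNA and 49.2% of mRNA calls lower), but without Dcr WT library 2 the odds ratio was 1.12 and Fisher's exact test gave p = 0.0781.

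**Figure D3:**
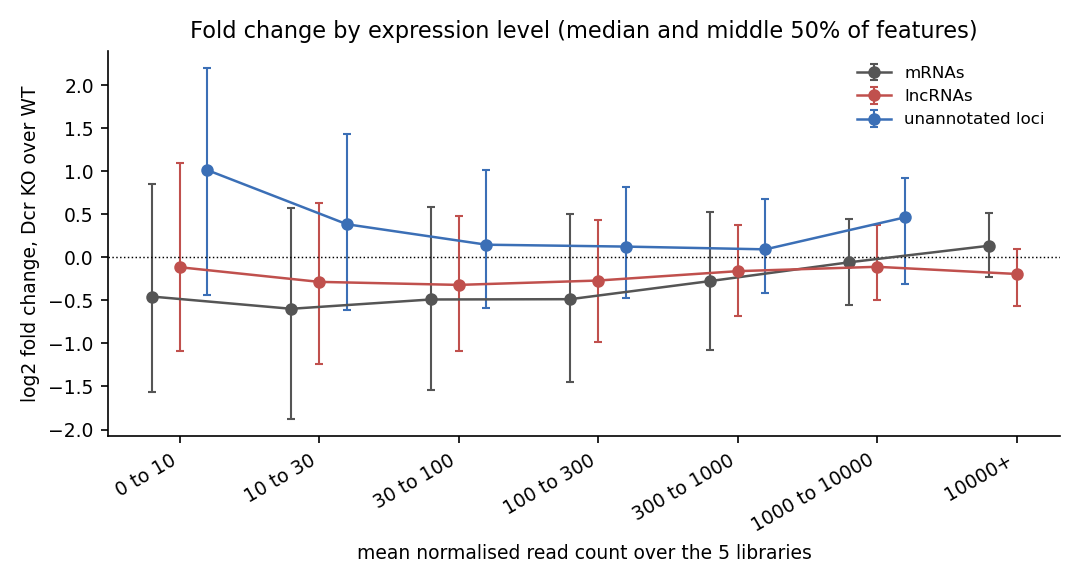
Median log2 fold change in Dcr KO over Dcr WT, with bars for the middle 50% of features, for mRNAs, lncRNAs and unannotated loci by mean normalised read count over the 5 libraries; points with fewer than 50 features are left out. For means between 30 and 100 the medians are −0.49 for mRNAs, −0.32 for lncRNAs and 0.15 for unannotated loci.

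The annotation source divided the lncRNAs further. Of 406 tested loci from the catalogue that the table calls lncRNAlocus, 81 fell and 11 rose, with a median of −0.73, below that of mRNA sets matched on expression (−0.50, percentile 0.82). Noncoding UCSC models fell in 206 and rose in 85 of 1055 cases, and noncoding RefSeq genes fell in 111 and rose in 66 of 621. Against mRNA sets matched on expression, the UCSC models (median −0.34, percentile 86.5) and RefSeq genes (−0.36, percentile 25.1) lay within the central 95%. MGI, VEGA, Bartel and Guttman records lay above it (−0.13, −0.20, −0.04 and −0.21). GenBank transcripts went the other way, with 124 higher and 104 lower of 1184 and a median of 0.01, above all matched sets. Unannotated loci were higher in 2828 and lower in 1357 of 18313 cases, with a median of 0.40, and repeat families were higher in 87 and lower in 35 of 429.

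Deletion of cMyc was examined in 1 library per genotype, so the differences have no replicate check and compare these libraries, not the genotypes. Myc had 446 reads in cMyc flox and 12 in cMyc KO, a ratio of 0.0219 (95% exact interval 0.0112 to 0.0387). Mycn was higher in cMyc KO (1.39, interval 1.33 to 1.45), as was Pou5f1 (1.24), while Dicer1 (0.917), Sox2 (1.07) and Nanog (1.12) lay closer to 1. Among other mRNAs above the median expression of all features, the ratios furthest below 1 were those of the tumour suppressor gene Rb1 (0.409), Zfp932 (0.417), Ttc14 (0.419), Nemf (0.432) and Kif20b (0.433). Those furthest above 1 were in Gfra1, the GDNF receptor gene (2.27), Enpp2 (2.25), Mid1 (2.23), the kinase gene Pim2 (2.08), and Tuba3a and Tuba3b (both 2.06), which share sequence and are uncertain.

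The typical lncRNA was lower in the cMyc KO library, while the class total was not: lncRNAs took 3.01% of reads in cMyc flox and 3.05% in cMyc KO. The median log2 ratio of lncRNAs was −0.32 over 1884 features (95% binomial interval −0.36 to −0.27), against 0.03 over 14360 mRNAs and 0.06 in mRNA sets matched on expression. Of 22 known lncRNAs, 12 were lower by at least 1.5-fold and 0 higher, with a list median of −0.63, below all random lists of mRNAs and lncRNAs (most of them mRNAs). The lncRNAs as a class were lower, so the list was also placed, after its values were seen, among random lists of other lncRNAs matched on expression; their median was −0.22 (95% of lists between −0.49 and 0.056), and the known lncRNAs lay at percentile 0.07. Snhg8 went from 310 to 175 reads (ratio 0.460, interval 0.380 to 0.556), Pvt1 from 160 to 107, Dancr from 166 to 120 and Firre from 1610 to 1186. Malat1 had a ratio of 0.669, whereas Meg3 (1.01) and Rian (1.18) were not lower. The lncRNAs of above-median expression with the largest ratios were linc878 and linc839 of the Bartel catalogue, Dubr, OTTMUST00000011068, which holds the same reads as Dubr, and uc007zzy.1, at 1.86 to 2.38. Those with the smallest were 9230108I15Rik, AK088487, uc009elc.1, 9330174C13Rik and uc007dva.1, at 0.204 to 0.333. Unannotated loci and repeat families also had medians below 0 (−0.40 and −0.46). The interval of linc839, with 12 and 28 reads, included 1.

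Gene lists were placed among random lists of mRNAs and lncRNAs of equal size and level. Because lncRNAs had the lower median, their presence can lower the random lists at weak expression and favour the upper tail. The median of the random lists was −0.03 for mesoderm genes and −0.02 for germline genes, against 0.05 for pluripotency genes. Random lists of mRNAs alone were not drawn. The Myc targets had a median log2 ratio of 0.05, inside the range of random lists (−0.02 to 0.15), with a mean of −0.06. Ncl (−0.56) and Npm1 (−0.45), both nucleolar, were lower; they were chosen after their values were seen. Only the known lncRNAs and the p53 targets (median −0.23, percentile 0.07; Ccng1 at 0.693, Zmat3 at 0.894, Rrm2b at 0.875) lay in the lower tail of the random lists, outside the central 95%. In the upper tail were 8 lists. Of these, germline genes left the tail without a filter (percentile 96.4) and with at least 50 reads (96.6), and mesoderm genes with at least 50 reads (95.8), while imprinted genes entered it in both settings. The fibroblast list had the highest median (0.64), with Vim at 1.68, Acta2 at 1.55 and Tagln at 1.01. It was followed by neural genes (0.41; Tubb3 at 1.33, Nes at 1.31, Olig2 at 1.11), mesoderm genes (0.31; Nodal at 1.24, Wnt3 at 1.22, Hand1 at 1.12) and TGF-beta and BMP genes (0.30; Id1 at 1.35, Tdgf1 at 1.23, Skil at 0.857). The others were ER stress and amino acid genes (0.27; Psat1 at 1.33, Asns at 1.11, Hspa5 at 0.939), germline genes (0.24; Tex19.1 at 1.26, Piwil2 with 318 and 469 reads, Ddx4 at 0.911), DNA methylation genes (0.21; Trim28 at 1.35, Dnmt3b at 1.27, Dnmt1 at 1.13) and pluripotency genes (0.17; Sall4 at 1.28, Utf1 at 1.24). The other 12 lists lay between these limits.

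The series title joins Dicer, Myc and lncRNAs in 1 circuit, which asks whether transcripts that fell in Dcr KO were also lower without cMyc. Snhg8, Dancr, Pvt1 and Firre were lower in both comparisons. As a class the lncRNAs called lower in Dcr KO were not lower in cMyc KO than other lncRNAs: their median was −0.28 over 502 features, against −0.32 in lncRNA sets matched on expression (95% of sets between −0.39 and −0.26, percentile 80.0). Below 0 were 70.7% of them and 69.8% of all lncRNAs. The lncRNAs called higher in Dcr KO had a median of −0.37 over 192 features (percentile 34.5). For mRNAs the directions were opposite, by small shifts. Those called lower in Dcr KO had a median of 0.08, above all matched sets (median 0.03, difference 0.049). Those called higher had a median of −0.02, below all of theirs (median 0.03, difference −0.049). With sets of 3569 and 3180 mRNAs, even small shifts lie outside all matched sets. Across genes, which are not independent replicates, the 2 log2 changes had a Pearson r of −0.041 and a Spearman rho of −0.058 for 1868 lncRNAs, and −0.114 and −0.121 for 14328 mRNAs. The cMyc side rests on 1 library per genotype, and each comparison was made within its own table. The cMyc libraries also differ from the Dcr libraries in cell line, read layout and depth. A lack of overlap is therefore not a result on Myc in the Dcr cells.

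**Figure D4:**
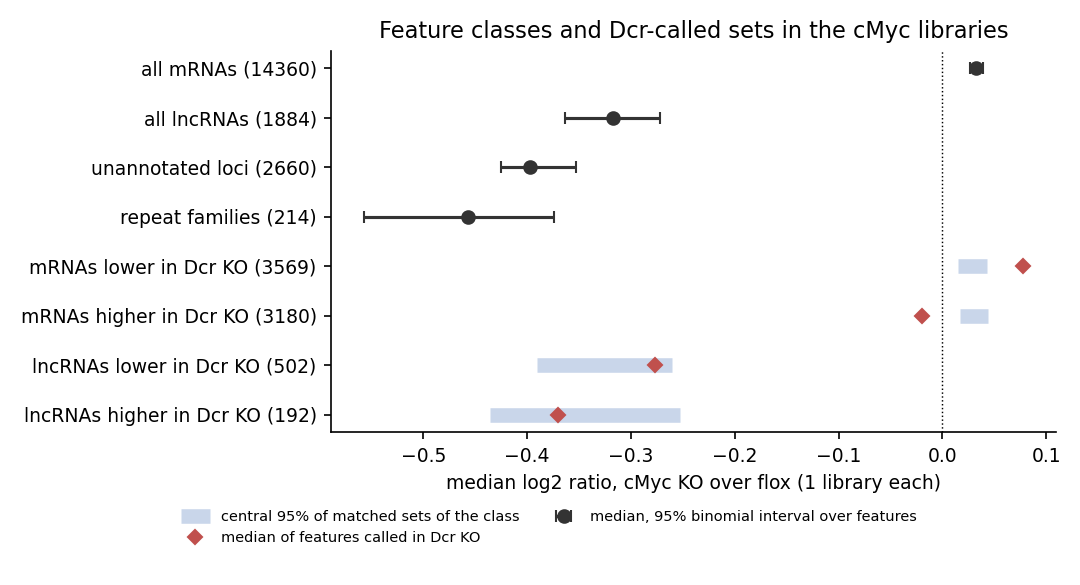
Median log2 ratio of cMyc KO over cMyc flox (1 library each) for 4 feature classes, with 95% binomial intervals over features as bars, and for the features called in Dcr KO as diamonds, with the central 95% of matched sets of the same class as bands. The number of features is in brackets; lncRNAs lie at −0.32 and mRNAs at 0.03, and the diamonds of the lncRNAs lie within their bands.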

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

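Of the alternatives below, edgeR, thinning, the narrower gene models, the list tests against mRNAs and lncRNAs alone, the random lists of lncRNAs and the deposited scaling of the cMyc table were chosen after seeing the data. Of 286 comparisons of summary results with an alternative, 243 stayed within the limits set for each (1.5 times for a count, the spread for a median, the side of the threshold for a test), 40 moved in size beyond them, 1 lost and 1 gained a call, and 1 reversed. Direction and side of the threshold were kept in 412 of 440 comparisons for the gene lists in Dcr KO, and the side of the random lists in 150 of 155 for those in cMyc KO. Of 105 named genes, 24 lost their call under some alternative and 0 changed sign. Nanog gained a call in 2, among them the fit without Dcr WT library 1, which leaves 1 wild-type library. Without Dcr KO line 1, 5 lost it, without line 3, 8, and without line 4, 8 (Mcm7, Rpl10l, Syce1, Firre, Hspa5, Dnmt1, Uhrf1, Phlda3, Tfap2c, Psat1, Gm4340, Zscan4c and Zscan4d), with adjusted p-values up to 0.132. The lncRNA median stayed above that of mRNA sets matched on expression in all 21 alternatives (0.17 to 0.30).

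The number of calls depended on the threshold and on the libraries, and which direction held more of them also on the scaling and the tool. At an adjusted p under 0.01, 3608 features were higher and 3229 lower, with 203 and 350 lncRNAs and 2192 and 2306 mRNAs; with an absolute log2 fold change of at least 1, 1770 and 2256 mRNAs remained. Stricter thresholds lower counts by construction. With RefSeq, MGI, VEGA and known lincRNA records alone, 239 lncRNAs were higher and 412 lower, since fewer were counted. edgeR called 6257 features higher and 6965 lower, and DESeq2 7011 and 6800.

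Leaving out 1 library at a time gave 3782 to 8022 features higher and 3847 to 5935 lower, 218 to 495 lncRNAs higher and 461 to 657 lower, and 2162 to 3810 mRNAs higher and 2504 to 4079 lower. The odds ratio ran from 1.12, without Dcr WT library 2 (Fisher's exact test, p = 0.0781), to 2.03, and the difference between lncRNA and mRNA medians from −0.26 to −0.089. Lists called higher ran from 1 to 2 and lists called lower from 0 to 2. Without a Dcr KO line fewer samples are tested; without a Dcr WT library the lone sample is assumed to vary like the others. For the other shifts the cause was not tested. No paired analysis was possible because the genotypes share only 1 replicate number.

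The gene lists were least stable. Against 1 list higher and 0 lower, there were 3 higher and 1 lower with upper quartile scaling and on DESeq2 statistics, 2 higher and 1 lower on edgeR statistics, with total count scaling, with no filter and with pseudocount 5, 2 higher and 0 lower with thinned libraries, 3 and 0 against mRNAs and lncRNAs alone, 4 and 2 with fry, and 0 and 0 with an estimated correlation. The lower list was that of Myc targets on edgeR statistics and with total count scaling, and of fibroblast genes in the other 4 of these settings with 1 lower; the cause was not tested. A first version of the DESeq2 and edgeR list tests ran limma on values those tools had normalised, so that DESeq2 repeated the unfiltered result. It was replaced by the tools' own statistics after values had been seen. With the replacement, G1/S genes passed with both tools, Myc targets with edgeR and interferon genes with DESeq2, and 2-cell-like genes no longer passed with DESeq2.

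In the cMyc libraries the lncRNA median was −0.38 with total count scaling, −0.24 with the deposited scaling and −0.22 without a filter. The mRNA median went to −0.031 with total count scaling, a reversal, to 0.00040 with scaling on mRNAs alone and to 0.11 with the deposited scaling, since a scaling moves every median. Without a filter, lncRNAs called higher in Dcr KO lay 0.062 above matched sets; the cause was not tested. Depth limits the cMyc libraries, at 24660365 and 31633011 reads, where a lncRNA such as linc839 had 12 and 28.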

Other observations

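The tests of the low lncRNA median in the cMyc KO library and the look at repeat families were chosen only after the results were seen. The raw difference between lncRNAs and mRNAs in Dcr KO was set against 3 explanations. Low expression may account for it: matched mRNA sets fell further, and lncRNAs lay 0.23 above them. The test was to count for this explanation if lncRNAs lay inside the matched sets and against it if they lay below; they lay above, so neither bound was met. Without the shallower Dcr WT library the difference was −0.26, so it did not shrink when that library was left out. The second condition written for a verdict, a place below the matched mRNA sets, was not met. The spread between lines (SD 0.09) shares the same wild-type mean, so it does not measure variation between wild-type libraries. This explanation is therefore not settled. Lower Myc stays open: lncRNAs called lower in Dcr KO lay 0.044 above matched lncRNAs in cMyc KO, and 1 library per genotype from another cell line cannot settle it.

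Unannotated loci were higher in Dcr KO, with a median 0.46 above that of mRNAs, or 0.15 among features with a mean of at least 50 and 0.31 without Dcr KO line 4. The difference was 0.25, 0.38 and 0.72 in lines 1, 3 and 4, and between the wild-type libraries alone, library 2 against 1, it was 0.21. Their share of reads overlapped between genotypes (0.432 and 0.528% in Dcr WT; 0.432, 0.482 and 0.601% in Dcr KO). Unequal depth could contribute: with libraries thinned to equal reads the difference was 0.39, and without the shallower Dcr WT library 0.27. Both exceed the bound of 0.2, but by less than the spread between lines, a condition applied after the values were seen, so neither explanation is settled. A background that raises every low-level feature was not seen in annotated features of equal level, whose matched sets had a median of −0.42. Unannotated loci, at 0.40, lay 0.81 above them. Loci assembled from the Dcr KO libraries would be selected for reads there, and the source libraries are not given. The comparison therefore cannot settle whether a background raised the unannotated loci. No biological explanation was tested for this pattern.

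The median lncRNA was lower in the cMyc KO library. Low read numbers are an unlikely source, as the difference from matched mRNAs was −0.34 among features with at least 50 reads. Unannotated loci and repeat families also had low medians (−0.40 and −0.46). Their shares of reads went from 0.342 to 0.255% and from 0.288 to 0.149%. The share of mRNAs went from 62.3 to 60.9%, but the shares include ribosomal RNA, whose share was higher in cMyc KO. The mRNA share therefore cannot decide whether less RNA came from outside annotated mRNAs in that library. The test for that explanation was the median of unannotated loci, which went with it. The share of lncRNAs did not fall (3.01% in cMyc flox and 3.05% in cMyc KO). Less RNA from outside annotated mRNAs is thus not shown for lncRNAs in total, and this explanation stays open. Loss of Myc may also act, but Myc targets lay at percentile 30.02 of random lists, which leaves it open with 1 library per genotype.

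Repeat families were looked at after their values were seen. Of 76 LINE-1 families 36 rose and 1 fell in Dcr KO, although L1Md_T, among the most abundant, fell from 69352 to 30421 (limma adjusted p = 0.00878; 0.0521 without Dcr KO line 4). The share of reads from all repeats was 0.171 and 0.166% in Dcr WT and 0.121, 0.147 and 0.153% in Dcr KO. Of 10 B1 and B2 families 7 fell, and of 7 MERVL and MT2 families 4 rose. MERVL-int went from 1488 ± 997 (SD, n = 2) to 5673 ± 1328 (SD, n = 3; limma adjusted p = 0.00305; log2 fold change 2.09, but 2.83 without Dcr WT library 1 and 1.34 without library 2), and B2_Mm1a from 4482 ± 332 to 487 ± 121 (limma adjusted p = 2.97e-05). Copies share reads, so single families are uncertain.

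Meg3, a lncRNA of the Dlk1-Dio3 locus, stood at 38980 and 32396 in Dcr WT libraries 1 and 2 and at 555, 63852 and 89316 in Dcr KO lines 1, 3 and 4. Rian stood at 26356 and 29036, and at 363, 40964 and 57066.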
